A study of Mus musculus with 6 samples.

How the data were processed

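Visium libraries of 6 thymus sections from wild-type C57BL/6 mice were read from the deposited files, 1 section for each of 2 ages and 3 days. The authors processed the reads with Space Ranger 1.3.1 on the GRCm38 (mm10) genome with GENCODE vM21 genes, per the submitters' notes. The deposited matrices hold raw UMI counts per gene and spot, for 32285 genes and for spots under tissue alone, with no normalization. Counts of reads and spots in the summary tables are totals that the authors' software wrote. The saturation, the share of reads in tissue spots and the share of reads mapped to the transcriptome are each deposited as a fraction and are printed here as percentages. For each gene and section the authors also deposited a score of spatial clustering, Moran's I, computed on values whose normalization is not stated. A p-value of Moran's I, raw and adjusted, stands beside it in the deposited tables and treats spots as the unit. The summary and the Moran's I table of the 18-month day 7 section are byte for byte those of the 18-month day 4 section and were not used here. Images and spot positions were not used here. Genes were keyed by Ensembl ID, since 38 symbols occur more than once.

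Spots of each section were clustered on their own, because a joint clustering parted sections before tissue. Spots with at least 200 UMIs were scaled to 2000 UMIs and log-transformed, 2000 variable genes were scaled (maximum 10), and 20 principal components and 15 neighbours were passed to Leiden clustering at resolution 0.6 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15). Immunoglobulin, ribosomal, mitochondrial and globin genes, a few other transcripts such as Malat1, and the genes of 10 lists reserved for testing were kept out of the clustering. T cell receptor genes stayed in. For each cluster, the median log2 fold against the rest of the section was taken over each of 18 lists of tissue genes (pseudocount 20 CPM, which are UMIs scaled by the total, list genes at 5 or more, at least 3 genes). A cluster was cortical when the higher of its cortical epithelial and double-positive thymocyte lists reached 0.2 and lay 0.4 above the medullary epithelial list. It was medullary when the medullary epithelial list reached 0.2, lay 0.4 above cortical epithelium and stood above double-positive thymocytes. The lists of double-negative thymocytes, mimetic epithelium and mature T cells entered only the checks that follow. Clusters were left out when a list of fat, brown fat, muscle, parathyroid and thyroid, fibroblasts or endothelium was higher, or when more of their 10 leading genes (at 100 or more CPM) belonged to another list. This rule was set after the clusters had been seen. The spots left out for want of a high enough list were 52.6% (2-month day 1), 19.6% (18-month day 1), 12.6% (2-month day 4), 59.1% (18-month day 4), 6.08% (2-month day 7) and 34.0% (18-month day 7). Such a tissue list was higher for 11.2% of the spots of the 18-month day 1 and 10.2% of the 2-month day 4 section, and other leading genes were found for 16.2% of the 2-month day 7 section. Spots under 200 UMIs (24 and 73 on day 1, 34 and 26 on day 4, and 57 and 124 on day 7, at 2 and 18 months) stayed in the sums of whole sections.

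UMIs were summed per section, or per section and region with at least 20 spots, and genes were kept by filterByExpr with a minimum count of 10. Sums were normalized by TMM and tested by edgeR 4.0.16 quasi-likelihood F tests (R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. Age was tested with day in the model, days with age in the model, and the 2 regions with section as a block. The interaction of age and region was tested on sums of both regions. For medullary against cortical regions, only genes of the 10 reserved lists were adjusted and called, because the other lists entered the clustering or the rule for regions. The difference in mean medullary share was tested by exact permutation of ages within days. The 28 lists were fixed before the data were examined, and were tested by camera (limma 3.58.1) with the preset correlation of 0.01, by camera with an estimated correlation, and by fry. Genes named in the report are the 8 largest changes per direction, up to 4 passing genes per list, and a fixed set of genes of the study's question. The largest changes had to pass, to have a mean of at least 10 CPM and to share 1 sign in every pair compared. Immunoglobulin, T cell receptor, ribosomal and mitochondrial genes and genes with Gm or Rik names were not eligible as largest changes. The standard error of a log2 fold change is its size divided by the square root of its F statistic. CPM of single sections carry exact Poisson intervals, and shares Clopper-Pearson intervals, at 95%. Within a day, list medians of log2 ratios (pseudocount 1, mean of at least 5 CPM) were set against 10000 random lists drawn from the 100 nearest genes in expression. A count of 0 in a group was replaced by a floor of 3 counts over the group for folds.

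The alternatives were RLE size factors, no count filter, DESeq2 1.42.0, limma-voom (statmod 1.5.0), each section left out, spots with at least 1000 UMIs, models without day, age or section, day as a linear number, cortical and medullary spots alone, all sections thinned to 2313732 UMIs, Leiden resolutions of 0.3 and 1, and regions drawn as the highest and lowest 25% of spots by list score. Leaving out immunoglobulin genes and leaving out both day 1 sections were added after the results were seen. Other packages were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

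The tests were tested on simulated data with 200 changed genes. The simulated sections shared 1 average profile and 1 common dispersion, and genes were drawn independently with no other difference between sections. The real spread also holds variation particular to each gene and any interaction of age and day. The rates below therefore hold for the simulated setting alone. For age in whole sections, 70.1%, 94.0% and 93.9% of changes of 1, 2 and 3 on the log2 scale were called, and 6.01% of calls were false. For the interaction these were 35.8%, 80.6% and 87.9%, with 6.85% false. A planted shift of 1 in the cell cycle list was called by camera in 4 of 4 comparisons. The estimated correlation gave adjusted p of 0.0644 to 0.114, so that this version of the test missed a shift of that size. By fry the shift was called for age (adjusted p = 0.0189), day 4 against day 1 (0.000877) and day 7 against day 4 (0.0291). It was missed by fry for day 7 against day 1 (0.0729). In the real sections fry passed 0 lists for age, although it called the planted shift there. The simulated genes were independent, so the power of fry on the real sections was not measured. For ratios within a day, 60 of 60 planted lists and 2 of 60 unplanted lists lay in the upper tail of random lists. These lists were themselves genes drawn at random, so the rate does not hold for lists of genes that move together. The smallest section held 2313732 UMIs and so gives the widest counting intervals.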

Results

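Spatial gene expression was measured on 6 sections of thymus from wild-type C57BL/6 mice, 1 section for each combination of 2 ages (2 and 18 months) and 3 days (1, 4 and 7). The series describes the mice as sampled after injury, while the sample labels give the treatment as untreated and name no kind of injury. On a Visium slide, polyadenylated RNA of a tissue section is captured on barcoded spots, so 1 spot holds RNA of several cells, and spots of 1 section are not replicates. The title of the series concerns regulatory T cells in thymic regeneration, and the design addresses how the tissue differs between ages and days. The 2-month sections held 1625, 841 and 1612 spots under tissue on days 1, 4 and 7, and the 18-month sections held 1815, 1613 and 1443. Their totals were 6189765, 2313732 and 3121529 UMIs (unique molecular identifiers) at 2 months, and 5388796, 4555342 and 3785777 at 18 months. The median per spot was 3186, 2264 and 1605 UMIs at 2 months, and 2361, 2003 and 1824 at 18 months. Mitochondrial genes took 1.88% to 2.89% of the UMIs of a section. Immunoglobulin genes took 0.153%, 0.354% and 0.392% at 2 months on days 1, 4 and 7, and 6.26%, 4.32% and 1.81% at 18 months. Xist was present and Ddx3y had 0 UMIs in all 6 sections.

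There is no replicate within an age and day. Age was therefore tested over 3 sections against 3 with day in the model, and days over 2 sections against 2 with age in the model. P-values measure the spread between these sections, which leaves 2 residual degrees of freedom. Intervals on single sections are exact, at 95%, and cover counting error alone.

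Spots were grouped in each section into a cortical and a medullary region. Cortical clusters had genes of cortical epithelium or double-positive thymocytes above medullary epithelium. Medullary clusters had genes of medullary epithelium above cortical epithelium and double-positive thymocytes. The 1 cortical cluster of the 2-month day 1 section stood apart. Against the rest of that section its erythroid genes were at 1.14 and its B and plasma cell genes at 1.03 (median log2 fold), above cortical epithelium at 0.57, while double-positive and double-negative thymocyte genes were at -0.43 and -0.38. In the medullary cluster of the 18-month day 7 section erythroid genes (1.89) stood above medullary epithelium (1.49) and B and plasma cell genes (1.20). The medullary region held 26.5% (95% Clopper-Pearson interval 24.4% to 28.7%), 21.0% (18.3% to 24.0%) and 14.0% (12.3% to 15.7%) of the spots of the 2-month sections on days 1, 4 and 7. At 18 months the same shares were 15.1% (13.5% to 16.8%), 24.7% (22.6% to 26.9%) and 16.2% (14.4% to 18.2%). The cortical region held 19.4%, 52.1% and 60.2% of spots at 2 months, and 50.1%, 14.5% and 41.2% at 18 months. At resolutions 0.3 and 1 the 2-month day 1 section had 0 cortical spots. Clusters left out of both regions held between 22.3% and 59.1% of the spots of a section, not counting spots under 200 UMIs. Averaged over the 3 days, the medullary share was 1.83 points lower at 18 months (a mean difference of -1.83), with the 18-month section higher on 2 of 3 days. The two-sided exact permutation test gave p = 1, where the smallest p the design allows is 0.25. The sign of this mean turned when day 1 was left out (2.97 points), when clusters were drawn at a finer resolution (0.792 points) and when the share was taken of cortical and medullary spots alone (3.02 points). It was -4.58 without day 4, -3.87 without day 7 and -7.30 at resolution 0.3, where 2 of the 18-month sections had 0 medullary spots.

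**Figure D1:**
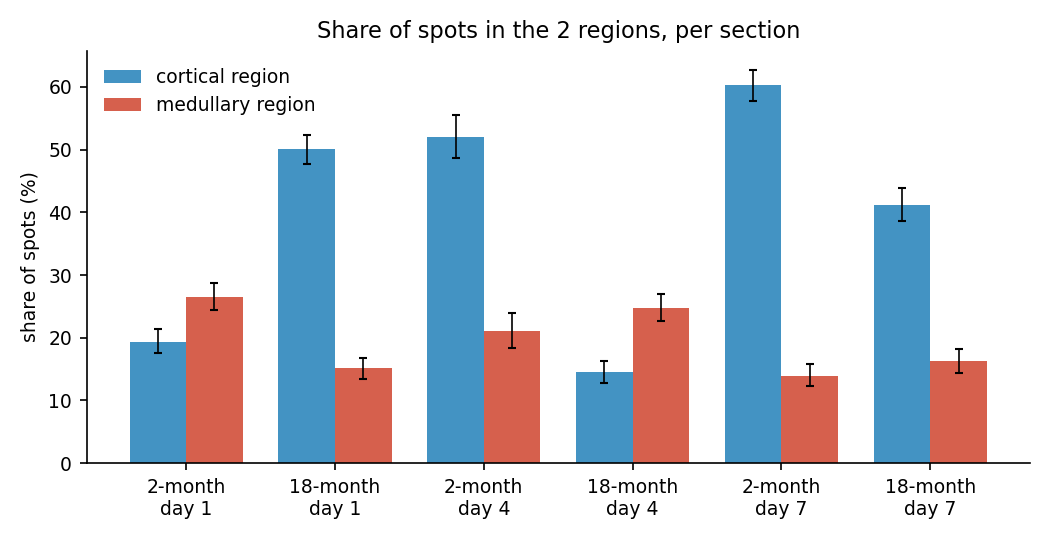
Share of spots (%) in the cortical and medullary regions of each of the 6 sections; error bars are 95% Clopper-Pearson intervals for counting error. The medullary share lies between 14.0% and 26.5%, and the cortical share between 14.5% and 60.2%.

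The first comparison asks how the thymus of 18-month mice differed from that of 2-month mice over the 3 days. Genes higher at 18 months included 3 of 10 tested B and plasma cell genes and 3 of 15 factors of thymic repair, and genes lower at 18 months included 3 of 10 of mimetic epithelium and 2 of 8 of neutrophils. Cd79a, a chain of the B cell receptor complex, was higher by 3.11 on the log2 scale (SE 0.39, n = 3 sections per age), and Ms4a1, which encodes CD20, by 3.03 (SE 0.35), each in 3 of 3 days. Bmp4, a ligand that thymic endothelial cells release to epithelium, rose by 2.25 (SE 0.39), and Fgf7, a growth factor for epithelial cells, by 4.09 (SE 0.65). Trpm5, a cation channel of tuft cells, fell by 2.68 (SE 0.34), and Krt16, a keratin of stressed epidermis, fell by 2.80 (SE 0.30), both lower in 3 of 3 days. Of 13724 genes tested, 255 passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 158 higher and 97 lower at 18 months. An unadjusted p under 0.05 was reached by 1563 genes. More genes were lower than higher without the 2-month day 4 section (82 higher, 93 lower), without the 18-month day 4 section (85 and 101) and in cortical and medullary spots alone (54 and 70).

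By the fixed rule for named genes, the largest increases were in Glycam1, Slpi, Nnat, Cd79a, Ms4a1, Derl3, Fcrla and Fam107a. Glycam1, a mucin of the high endothelial venules through which lymphocytes enter lymph nodes, had 481 UMIs over the 18-month sections and 0 over the 2-month sections, at least 136-fold higher against a floor of 3 counts over the group (adjusted p = 1.20e-05). Slpi, a protease inhibitor, was higher by 3.63 (SE 0.31, adjusted p = 0.00172), and Nnat, an imprinted gene of neural and endocrine cells, by 3.56 (SE 0.23, adjusted p = 8.04e-06). Derl3, a component of protein disposal in secretory cells, rose by 2.74 (adjusted p = 0.000401). The increase was 2.74 for Fcrla, a B cell protein (adjusted p = 0.00385), and 2.72 for Fam107a (adjusted p = 0.000134). Among the largest decreases, Saa1, an acute phase protein, fell by 3.51 (SE 0.33, adjusted p = 0.000453) and Spink1, a trypsin inhibitor, fell by 3.25 (SE 0.32, adjusted p = 0.000257). Rptn and Asprv1, which encode proteins of the cornified layer of skin, were at -3.14 and -3.02 (adjusted p = 0.000417 each). Resp18, a protein of endocrine secretory granules, was at -2.79, Lypd8, a protein of gut epithelium, at -2.64, and Gng13, a G protein subunit of taste cells, at -2.50 (adjusted p = 0.00266, 0.00512 and 0.000257). The same sign on 3 of 3 days was a condition for naming these genes, so it is no added support for them. Of all 255 genes, 253 had it. In the GRCm38 build, Glycam1 (ENSMUSG00000022491) lies on chromosome 15 at 103562759 to 103565081, Cd79a (ENSMUSG00000003379) on chromosome 7 at 24897381 to 24902197, Bmp4 (ENSMUSG00000021835) on chromosome 14 at 46383520 to 46390669, Fgf7 (ENSMUSG00000027208) on chromosome 2 at 126034658 to 126091185 and Trpm5 (ENSMUSG00000009246) on chromosome 7 at 143069153 to 143094642.

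**Figure D2:**
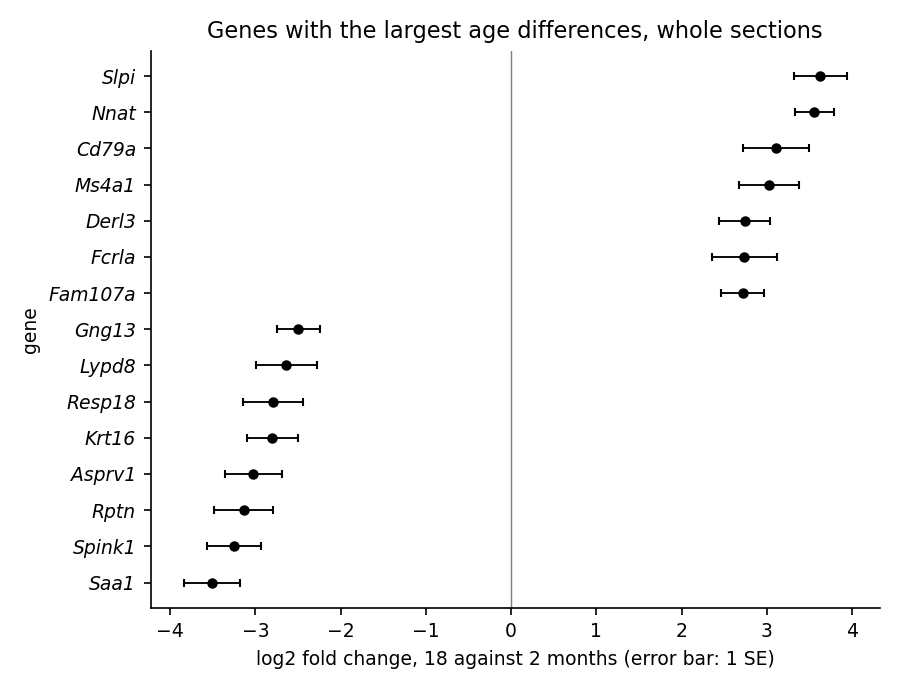
Fitted log2 fold change of 18 against 2 months in whole sections, over 3 sections per age. Genes are those with the largest differences under the rule for naming, which asks for a mean of at least 10 CPM. Error bars are 1 SE. Glycam1 is left out because its count was 0 in every 2-month section. Values run from -3.51 (Saa1) to 3.63 (Slpi).

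Among the 28 gene lists fixed in advance, 11 passed for age by camera with its preset correlation of 0.01 (7 higher, 4 lower), and 0 passed with an estimated correlation or by fry. Of 10 tested B and plasma cell genes, 3 rose (Cd79a and Ms4a1 among them), 0 fell and 7 did not pass. Adjusted over the list alone, 8 rose. All 10 were positive, with a median of 3.03 (camera adjusted p = 6.90e-34, adjusted p = 0.458 with an estimated correlation). The immunoglobulin share of all UMIs was higher at 18 months on each day, as given above.

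Of 10 tested genes of mimetic epithelium, the medullary cells that resemble peripheral tissues, 3 fell and 7 did not pass, and 5 fell adjusted over the list alone. The 3 were Trpm5 (adjusted p = 0.00115), Avil, an actin regulator of tuft cells, at -2.77 (SE 0.46), and Gnb3, a G protein subunit of taste and tuft cells, at -2.82 (SE 0.56). The list median was -0.86 with all 10 negative (camera adjusted p = 4.30e-10, adjusted p = 0.458 with an estimated correlation). Of 12 medullary epithelial genes, 4 fell, also adjusted over the list alone. Among these were Ccl21a, a chemokine that draws thymocytes to the medulla (-1.15, SE 0.17), Krt17 (-1.27) and Fezf2, a regulator of tissue antigen expression (-0.93). The medullary median was -0.44 (camera adjusted p = 1.59e-06, adjusted p = 0.458 with an estimated correlation). Aire, the other such regulator, was at -0.15 and did not pass (adjusted p = 0.870).

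No cortical epithelial gene of 10 passed, while 9 were positive and the median was 0.61 (camera adjusted p = 0.00134, adjusted p = 0.619 with an estimated correlation). Foxn1, the master regulator of thymic epithelium, was at 0.38 (adjusted p = 0.741, higher on 1 of 3 days), Ccl25, a chemokine that draws progenitors, at 0.76 (adjusted p = 0.813), and Dll4, the Notch ligand of the cortex, at 0.50 (adjusted p = 0.496). Without either day 1 section the list call ended, with camera adjusted p of 0.401 without the 2-month and 0.314 without the 18-month section.

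Of 15 tested factors of thymic repair, 3 rose (Bmp4, Fgf7 and Il33, an alarmin, by 1.04) and 12 did not pass, and 4 rose and 1 fell adjusted over the list alone (median 0.20, camera adjusted p = 0.00348, adjusted p = 0.458 with an estimated correlation). By day the ratio of the list was 0.34, 0.44 and -0.14 on days 1, 4 and 7, with day 7 the other way. Fewer of these genes were tested within regions. In the cortical region 0 of 10 passed for age (median 0.08), and in the medullary region 0 of 11 rose and 1 fell (median 0.11). Adjusted over the list alone, 0 passed in the cortical region, and 1 rose and 3 fell in the medullary region. The adjusted p was 0.0086 for Bmp4 and 0.00866 for Fgf7. Il7, a cytokine that thymocytes need, was at -0.19 (adjusted p = 0.752). In CPM (UMIs scaled by the section's total), Bmp4 was at 2.10 (1.12 to 3.59) against 18.0 (14.6 to 22.0) in the 2- and 18-month sections of day 1, at 4.32 (2.07 to 7.95) against 13.4 (10.2 to 17.2) on day 4, and at 1.60 (0.520 to 3.74) against 4.49 (2.62 to 7.19) on day 7. Fgf7 had 3, 0 and 3 UMIs in the 2-month sections of days 1, 4 and 7, and 74, 45 and 11 in the 18-month sections.

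Of 8 neutrophil genes, 2 fell, S100a8 at -2.14 (SE 0.20) and S100a9 at -2.10 (SE 0.28), 2 subunits of calprotectin, and 5 fell adjusted over the list alone. The median was -1.36 (camera adjusted p = 4.30e-10, adjusted p = 0.458 with an estimated correlation). Of 10 macrophage genes, 1 rose (Cd163, a scavenger receptor, by 2.33), and 6 rose and 1 fell adjusted over the list alone (median 0.40, camera adjusted p = 0.000765, adjusted p = 0.458 with an estimated correlation). Among 4 erythroid genes, 1 rose (Hbb-bt, a beta globin, by 2.66), and 3 rose adjusted over the list alone (median 2.77, camera adjusted p = 4.30e-10, adjusted p = 0.458 with an estimated correlation). By day the erythroid ratio of 18 over 2 months was 1.94, -0.50 and 3.68 on days 1, 4 and 7, so that day 4 went the other way. The median of 18 cell cycle genes was -0.26 with all 18 negative and none past the threshold (camera adjusted p = 0.00134, adjusted p = 0.727 with an estimated correlation), and by day the ratio was -0.50, -0.46 and 0.20, with day 7 the other way. Adipocyte genes had a median of 0.66 and parathyroid and thyroid genes one of 2.43, with 0 of 11 and 0 of 3 past the threshold (camera adjusted p = 0.000806 each, adjusted p = 0.727 and 0.458 with an estimated correlation). Adjusted over the list alone, 1 adipocyte gene rose and 1 parathyroid and thyroid gene fell.

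Regulatory T cell genes did not pass as a list for age (11 tested, 0 past, median 0.12 with camera's direction down, camera adjusted p = 0.681). Foxp3, the defining factor of these cells, was at 0.14 (SE 0.36, adjusted p = 0.935, higher on 1 of 3 days), and Il2ra, the interleukin 2 receptor alpha chain, at -0.51 (SE 0.16, adjusted p = 0.187). Foxp3 had 41, 12 and 9 UMIs at 2 months and 51, 21 and 9 at 18 months on days 1, 4 and 7. Of 8 genes of tissue regulatory T cells, 1 rose (Cxcr3, a chemokine receptor also of effector T cells, by 1.81), and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0568). Single members of other lists also passed. Il7r rose by 0.72, Itgax by 0.73, Prg2, an eosinophil granule protein, by 1.69, Dcn by 1.34, Pdgfra by 0.99 and Cdh11 by 1.16, while Postn fell by 0.74. The other 13 lists that did not pass for age were double-negative, double-positive and mature T cells, dendritic cells, eosinophils, endothelium, fibroblasts, brown fat, muscle, p53 targets, interferon, senescence and inflammation, and epithelial to mesenchymal transition, with camera adjusted p from 0.0584 (fibroblasts) to 0.963 (mature T cells). The median of MHC class II genes was 0.25 (camera adjusted p = 0.0614) and that of immediate early genes -0.09 (camera adjusted p = 0.310). Cdkn1a, which encodes the cell cycle inhibitor p21, was at -0.08 (adjusted p = 0.930), and Mki67, a marker of proliferation, at -0.27 (adjusted p = 0.554).

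Over the cortical and medullary spots alone 124 genes passed for age, and with day as a linear number 15 did. Within a day the ages are 1 section against 1 and were not tested. The median log2 ratio of the B and plasma cell list, 18 over 2 months, was 3.13, 2.58 and 1.62 on days 1, 4 and 7, each above 100% of 10000 random lists of matched expression. Random lists hold genes drawn singly, which need not move together as genes of 1 cell type can, so this place is no measure of significance. The cell cycle list, whose sign turned, lay above 0%, 0% and 99.9% of them on days 1, 4 and 7. The mimetic epithelial list was at -1.71, -0.47 and -0.50, and the neutrophil list at -1.70, -0.66 and -1.09. The day 1 pair stood apart for cortical epithelial genes (1.59 on day 1, against 0.09 and 0.15 on days 4 and 7), for interferon genes (-1.13, against 0.40 and 0.07) for adipocyte genes (2.27, against -0.29 and -0.25), for medullary epithelial genes (-0.95, against -0.02 and -0.22) and for brown fat genes (2.58, against -1.23 and -0.36).

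Within the cortical region, 2 of 5 tested neutrophil genes were lower at 18 months, and 2 of 2 parathyroid and thyroid genes and 1 of 7 B and plasma cell genes were higher. No list test was run for the regions. S100a8 was at -3.72 (SE 0.33) and S100a9 at -3.74 (SE 0.39), Timp1, a protease inhibitor of inflamed stroma, at -3.43, Ccl7, a monocyte chemokine, at -2.98, Slfn4 at -2.71, Lcn2, an iron-sequestering protein of neutrophils, at -2.35, Acta2, smooth muscle actin, at -2.35 and Chst2 at -2.14, each lower on 3 of 3 days, as the rule for naming requires. Pth, the parathyroid hormone gene, was higher by 3.49 (SE 0.37), Chga, a protein of endocrine granules, by 3.27, Slpi by 2.84, Iglc2, a light chain gene, by 2.19, C4b, a complement gene, by 1.78 and Cd5l, a macrophage protein, by 1.51. Of 11525 genes, 20 passed, 9 higher and 11 lower (edgeR quasi-likelihood, adjusted p from 0.000282 for S100a8 to 0.0419 for Krt17, at -1.20, among the named genes). An unadjusted p under 0.05 was reached by 697. With any 1 section left out 63 to 124 genes passed, and with day out of the model 0 did (41 with an unadjusted p under 0.05), against 29 by DESeq2 and 37 by limma-voom with day in. At resolutions 0.3 and 1, with 5 sections, 82 and 70 passed, of which 13 were among the 20 each time, and with regions by score 22 passed, 8 of them among the 20. More genes were higher than lower with regions by score (17 higher, 5 lower), at resolutions 0.3 (54 and 28) and 1 (58 and 12), by DESeq2 (17 and 12), without the 2-month (46 and 24) or the 18-month day 1 section (43 and 25) and without both (39 and 20).

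In the medullary region 2 of 9 tested B and plasma cell genes were higher at 18 months and 5 of 10 mimetic epithelial genes lower. Mzb1, a chaperone of plasma cells, was higher by 4.05 (SE 0.29, adjusted p = 1.69e-07), Cd79a by 2.66 (SE 0.40) and Cd79b by 1.83. The other large increases were Lepr, the leptin receptor (3.36), Ecel1 (3.15), Inmt (3.11), Pth (3.07), Pcsk6, a proprotein convertase (2.69), and C4b (2.66). Calm4, a calmodulin of keratinocytes, fell by 6.26 (SE 0.66, adjusted p = 1.37e-05), and Klk6, a kallikrein protease, fell by 4.02. Of the genes of tuft cells, Sh2d6 was at -4.24, Rgs13 at -3.81, Trpm5 at -3.66, Avil at -3.64, Gnb3 at -3.54 and Pou2f3, the tuft cell regulator, at -2.42. Saa1 was at -3.63 and S100a8 at -3.56. Over the list alone, 8 mimetic epithelial genes fell and 8 B and plasma cell genes rose. Of 12 medullary epithelial genes 3 fell, Krt17 at -1.30, Fezf2 at -1.19 and Ccl21a at -1.16 (7 adjusted over the list alone). Single members of other lists were Enpep (1.22), Dcn (1.11), Cxcr3 (2.06), Cox8b (1.68) and Zeb2 (1.19), which were higher, and Postn (-0.97), Calca (-2.31), Fst (-1.92, higher on 1 of 3 days) and Pmaip1 (-1.15), which were lower. Aire was at -0.09 (adjusted p = 0.948). The 18-month day 1 section had a cluster of 204 spots with mimetic genes at 0.42 that was left out, since its muscle genes were higher, while the 2-month day 1 section kept one at 0.97. With such clusters kept the mimetic median for age was -1.40, against -1.38 without them. Of 10184 genes, 161 passed, 55 higher and 106 lower (edgeR quasi-likelihood), and 1020 had an unadjusted p under 0.05. DESeq2 called 65, and without the 18-month day 7 section 426 passed. More genes were higher than lower with regions by score (161 higher, 118 lower), without the 2-month day 1 section (63 and 52) and with day out of the model (3 and 1).

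Medullary and cortical regions were compared on 116 tested genes of the 10 lists that were kept out of the clustering. Higher in the medullary region were 5 of 11 regulatory T cell genes, 5 of 8 MHC class II genes and 3 of 9 immediate early genes. Ccl5 (ENSMUSG00000035042), a T cell chemokine, was higher by 2.20 (SE 0.30). The 5 regulatory T cell genes were Tnfrsf4, which encodes OX40 (2.06, SE 0.39), Tnfrsf9, which encodes 4-1BB (1.96, SE 0.25), Izumo1r, the folate receptor of these cells (1.78), Tnfrsf18, which encodes GITR (1.19), and Foxp3 (1.70, SE 0.53), each in 6 of 6 sections. Adjusted over the list alone, 5 were higher and 1 was lower. The medians of the regulatory T cell and MHC class II lists were 1.02 and 0.90. Mature T cell and dendritic cell genes, which were not kept out of the clustering, had medians of a like size, 1.04 and 1.10. For Foxp3 the adjusted p was 0.0473 over the left-out lists and 0.0827 over all genes. Foxp3 had few UMIs even in whole sections, as given above, so its sign in a single section rests on few counts. In the deposited tables of Moran's I, given below, its adjusted p was under 0.05 in none of the sections used. Among the MHC class II genes were H2-Eb1 (1.26), H2-Oa (1.25), H2-Aa (1.15) and Cd74 (0.97), and 6 passed when adjusted over the list alone. Of 14 repair factors 3 were higher, Il23a, a subunit of interleukin 23 (3.27), Fst, an activin antagonist (1.68), and Igf1 (0.99). Itgae, an integrin of cells near epithelium, was at 1.51, and Ier2 at 0.78, Junb at 0.89 and Jun at 0.97 were the 3 immediate early genes. Jun, Vim (0.83) and Cdkn2b (1.92) were higher in 5 of 6 sections and Bax, a p53 target, in 6 (0.50). Pcna, a replication factor, was the 1 gene called lower (-0.58, in 6 of 6 sections), and no interferon gene of 11 passed. All 18 cell cycle genes, Pcna among them, were negative (median -0.57), with 0 past the threshold when adjusted over that list alone. In all, 22 passed, 21 higher and 1 lower (edgeR quasi-likelihood with section as a block, adjusted over the left-out lists), and 48 had an unadjusted p under 0.05. Exchanging the 2 regions in the 2-month day 1 section alone gave 29 genes, and leaving that section out gave 49.

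The last region comparison asks whether the age difference itself differed between medullary and cortical regions, and 24 of 12436 genes passed this interaction (14 positive, 10 negative; edgeR quasi-likelihood). Of 10 tested B and plasma cell genes 3 had an age difference more positive in the medullary region, as did 1 of 11 interferon genes and 1 of 9 of senescence and inflammation. Examples of a more positive difference were Ccl7 (2.51, SE 0.39), the monocyte chemokine Ccl2 (2.44, SE 0.46, but -0.67 at resolution 1), Pdpn, a stromal glycoprotein (2.35, SE 0.31), Rsad2, an interferon-induced gene (2.03), and the heavy and light chain genes Ighm (1.59) and Igkc (1.58). More negative were Cyp2a5 (-2.97, SE 0.40), Scx, a tendon factor (-2.95), Sbsn (-2.13) and Cst6 (-1.89), 2 proteins of keratinized epithelium, and Tnfrsf4 (-2.06, SE 0.43). All 24 had the same sign on 3 of 3 days, and 906 genes had an unadjusted p under 0.05. Foxp3 was at -2.63 (SE 0.88) and did not pass (adjusted p = 0.371). Without one of the 4 sections of days 4 and 7, 45 to 98 genes passed. Without the 2-month day 1 section 23 passed and without the 18-month one 26, and 8 of the 24 were among them each time. At resolution 1, with 5 sections, 28 passed, 7 of them among the 24. The negative genes were the more numerous at resolution 1 (13 positive, 15 negative), without a count filter (35 and 36) and without the 2-month day 4 section (45 and 47).

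Between day 1 and day 4 all 18 cell cycle genes rose and 8 of 11 interferon genes, 6 of 8 neutrophil genes and 10 of 19 p53 targets fell. Mki67 rose by 2.77 (SE 0.19, n = 2 sections per day), from 29.9 and 24.9 CPM at 2 and 18 months to 218 and 176. Dntt, which adds nucleotides at receptor gene joints, rose by 4.34 (SE 0.27) and Ptcra, the pre-T cell receptor chain, by 4.11 (SE 0.33). Irf7, a regulator of interferon genes, fell by 2.45 (SE 0.24), and Cdkn1a fell by 1.82 (SE 0.24). Of 13724 genes 3813 passed, 2016 higher and 1797 lower (edgeR quasi-likelihood), and 5439 had an unadjusted p under 0.05. More genes were lower than higher with RLE size factors (1802 higher, 2013 lower), by DESeq2 (1099 and 1164) and without the 2-month day 7 section (1950 and 2027). The other largest increases were Hist1h2bj, a histone (4.88), Pif1, a helicase (4.39), Prss57 (4.33), Dgkeos (4.15), Gzma, granzyme A (3.96), and Arpp21 (3.93), each with adjusted p under that of Pif1 or equal to it, 1.43e-05. The largest decreases were Hba-a2, an alpha globin (-6.14), Slfn4 (-5.48), Lcn2 (-3.85), Saa3 (-3.61), Siglec1, a sialoadhesin of macrophages (-3.61), S100a9 (-3.43) and Ms4a4c (-3.37), with adjusted p from 2.55e-06 (Slfn4) to 0.00961 (Saa3). Slc6a19, an amino acid transporter, had 17 UMIs on day 1 and 0 on day 4, at least 3.36-fold lower against 3 counts over the group (adjusted p = 0.0470).

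As lists, 19 passed between days 1 and 4 by camera (5 higher, 14 lower), 0 with an estimated correlation and 1 by fry (dendritic cells). All 18 cell cycle genes rose, also adjusted over the list alone, with a median of 2.47 (camera adjusted p = 9.26e-36, adjusted p = 0.413 with an estimated correlation). Ccnb1 was at 3.14, Rrm2 at 2.92 and Top2a at 2.92. Of 10 double-positive thymocyte genes 4 rose and 2 fell, with Rag2 at 3.22 and Cd4 at -1.48, and of 7 double-negative genes 3 rose, with Dtx1, a Notch target, at 1.18 and Notch3 at 0.75 (camera adjusted p = 0.00280 and 0.0178, adjusted p = 0.413 each with an estimated correlation). Adjusted over the list alone these counts were the same. Of 11 interferon genes 8 fell (11 adjusted over the list alone), with Ifi44 at -2.78 and Oasl2 at -2.02 (median -2.45, camera adjusted p = 2.74e-14, adjusted p = 0.413 with an estimated correlation). Of 8 neutrophil genes 6 fell (8 over the list alone), with S100a8 at -2.85, Csf3r at -2.42 and Mmp9 at -1.33, and of 19 p53 targets 10 fell (12 over the list alone), with Sesn2 at -1.32 and Zmat3 at -1.17 (camera adjusted p = 7.43e-08 and 9.85e-06, adjusted p = 0.413 each with an estimated correlation).

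Among stromal lists on day 4 against day 1, 5 of 13 fibroblast and matrix genes fell and 2 rose, with the collagens Col1a1 at -2.66, Col1a2 at -1.82 and Col3a1 at -1.68. Of 11 endothelial genes 5 fell (Plvap at -1.48, Selp at -1.61), of 10 macrophage genes 6 fell (C1qc at -1.42, Adgre1 at -1.31), and of 9 dendritic cell genes 3 fell and 1 rose (Fscn1 at -2.53, Ccl22 at -1.42, Ccl17 at 1.08). Under adjustment over the list alone, the endothelial count was 6, that of dendritic cells 4 lower and 1 higher, and the others were the same. For these 4 lists the camera adjusted p was 0.0141, 0.00280, 0.000787 and 0.0137, and the adjusted p = 0.413 with an estimated correlation. Of 10 mature T cell genes 7 fell (Ms4a4b at -1.80, Klf2 at -1.15), of 11 mesenchymal transition genes 6 fell and 1 rose (Tgfbi at -2.22, Sparc at -1.26, Zeb1 at 0.97), of 9 immediate early genes 5 fell (Egr1 at -1.56, Jun at -1.29) and of 9 senescence and inflammation genes 2 fell (Il1b at -1.31 among them). Within the list alone, 1 mature T cell gene also rose, 6 immediate early genes fell and the other counts were the same. Their camera adjusted p was 0.000579, 0.00871, 0.00124 and 0.00359, and the adjusted p = 0.413 with an estimated correlation. Of 12 medullary epithelial genes 6 fell (Ubd at -1.50, Tnfrsf11a at -1.36, Ccl21a at -1.03; 6 over the list alone; camera adjusted p = 0.00280, adjusted p = 0.424 with an estimated correlation). Of 4 erythroid genes 2 fell (3 over the list alone) and of 3 parathyroid and thyroid genes 1 (also over the list alone; camera adjusted p = 1.25e-06 and 0.00449, adjusted p = 0.413 each with an estimated correlation). Adipocyte and brown fat genes had medians of 1.85 and 2.90 with no member past the threshold (camera adjusted p = 0.000579 and 0.00755, adjusted p = 0.465 each with an estimated correlation). The 9 other lists had camera adjusted p from 0.0594 (cortical epithelium) to 0.684 (mimetic epithelium, median -0.23 with camera's direction up). Genes of theirs that passed included Il2ra (1.62), Lrmp (1.72) and Dll4 (1.05), which rose, and Tnfrsf4 (-1.51), Tnfrsf18 (-1.07), Ms4a1 (-1.85) and Ltb, a lymphotoxin chain (-0.93), which fell. In these lists 3 B and plasma cell, 3 regulatory T cell, 2 tissue regulatory T cell, 4 repair and 1 MHC class II gene fell, and 2 regulatory T cell, 1 cortical epithelial, 1 mimetic epithelial and 1 repair gene rose. The count was 2263 by DESeq2, 1173 without the 2-month day 4 section and 2169 without the 18-month day 4 section.

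**Figure D3:**
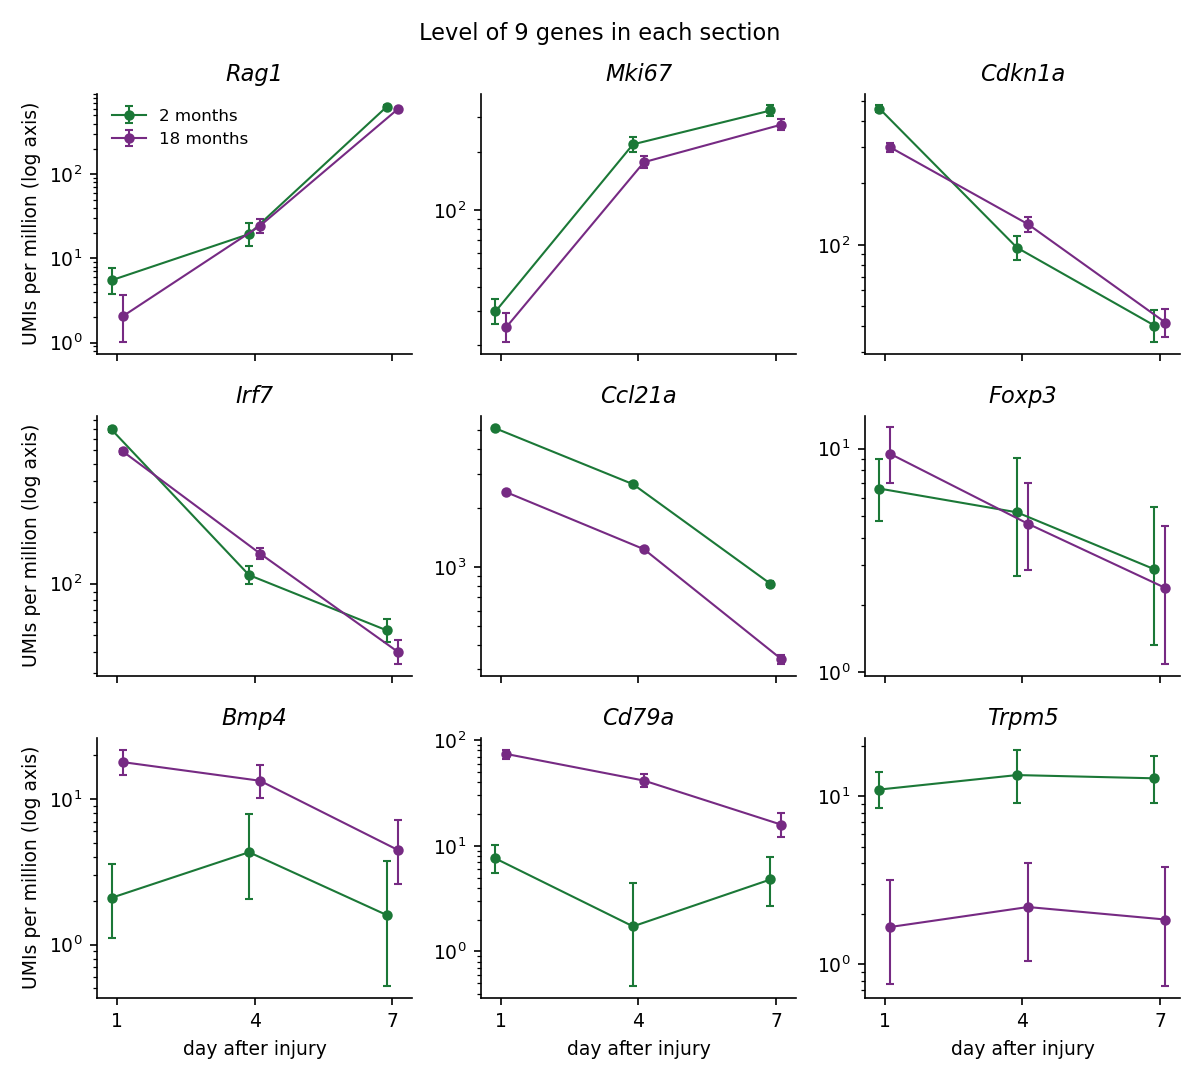
CPM (log axis) of 9 genes against day after injury (1, 4 and 7) in the 2-month and 18-month sections, 1 section per point; error bars are exact 95% Poisson intervals for counting error. Rag1 lies under 6 CPM on day 1 and at 590.9 or more on day 7 at both ages, and Cdkn1a and Irf7 decline.

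By day 7 the double-positive thymocyte genes Rag1 and Rag2 were among the largest increases, and most tested genes of interferon response, macrophages, vessels and fibroblasts were lower than on day 1. Rag1 and Rag2, which cut receptor genes for recombination, rose by 7.25 (SE 0.36) and 6.95 (SE 0.34). Rag1 (ENSMUSG00000061311, chromosome 2 at 101638282 to 101649501) went from 5.49 (3.80 to 7.68) to 631.4 (604 to 660) CPM at 2 months, and from 2.04 (1.02 to 3.65) to 590.9 (567 to 616) at 18 months. Mki67 rose by 3.38 (SE 0.20), and Cdkn1a fell by 3.28 (SE 0.26). Ccl21a fell by 2.81 (SE 0.21), and Foxp3 fell by 1.68 (SE 0.44, adjusted p = 0.00563). Of 13724 genes 8012 passed, 4248 higher and 3764 lower (edgeR quasi-likelihood), and 8669 had an unadjusted p under 0.05. The lower genes were the more numerous with RLE size factors (3812 higher, 4068 lower), by DESeq2 (2770 and 3066) and without the 2-month day 4 section (3681 and 3941). The other largest increases were Dgkeos (6.49), Tdrd5 (6.43), Dntt (6.03), BC028471 (5.94), Arpp21 (5.77) and Tctex1d1 (5.63). The largest decreases were Rsad2 (-6.80), Timp1 (-6.27), Slfn4 (-6.04), Saa3 (-5.72), Lcn2 (-5.55), Fcgr4, an Fc receptor (-5.40), Batf2, an interferon-induced factor (-5.34), and Ms4a4c (-5.25), each lower in 2 of 2 ages, as the rule for naming requires. Xist was at 0.89 (adjusted p = 0.00698).

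Between days 1 and 7, 20 lists passed by camera (3 higher, 17 lower), 16 by fry and 0 with an estimated correlation. Of 10 double-positive thymocyte genes 9 rose (median 3.91), and all 18 cell cycle genes rose, with Top2a at 3.36 and Rrm2 at 3.17 (median 2.70). All 11 interferon genes fell, with Ifi44 at -4.44 and Irf7 at -3.97 (median -3.95). These counts were the same adjusted over the list alone. The camera adjusted p was 2.50e-16, 2.50e-16 and 2.20e-11, and the adjusted p = 0.369 with an estimated correlation for each. Of 10 macrophage genes 9 fell (C1qa, a complement gene, at -3.00; median -2.11), of 11 endothelial genes 10 fell (Plvap at -2.95, Selp at -3.73; median -1.63), of 13 fibroblast and matrix genes 12 fell and 1 rose (Col1a1 at -3.85, Postn at -2.13; median -1.50), and of 8 neutrophil genes 7 fell (Csf3r at -3.88; median -2.36). Of 12 medullary epithelial genes 10 fell (Ubd at -2.62 among them), of 10 mature T cell genes 8 fell (Ms4a4b at -3.25, S1pr1 at -2.85) and of 9 dendritic cell genes 6 fell (Fscn1 at -3.81). Over the list alone, 9 mature T cell genes fell and the other counts of these lists were the same. For these 7 lists the camera adjusted p lay between 2.43e-07 (macrophages) and 0.00323 (dendritic cells), and the adjusted p = 0.369 with an estimated correlation.

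All 8 MHC class II genes fell by day 7 (H2-Aa at -1.63, Cd74 at -1.53), as did 6 of 9 senescence and inflammation genes (Cdkn2a at -2.76 among them) and 10 of 11 mesenchymal transition genes, while Zeb1, a repressor also of thymocytes, rose by 2.20 (camera adjusted p = 0.00121, 0.000761 and 0.00121, adjusted p = 0.434 each with an estimated correlation). These counts were the same adjusted over the list alone. Of 11 regulatory T cell genes 8 fell and 1 rose (Tnfrsf4 at -2.16, Tnfrsf9 at -2.76, Capg at -1.68), of 8 tissue regulatory T cell genes 6 fell (Rora at -1.87, Itgae at -1.32, Il10 at -2.19), and of 15 repair factors 10 fell (Igf1 at -1.87, Il33 at -1.68, Il7 at -1.01, Bmp4 at -1.60). With adjustment over the list alone, 8 fell and 2 rose, 6 fell, and 11 fell. Their camera adjusted p was 0.0248, 0.0422 and 0.00307, and the adjusted p = 0.369 with an estimated correlation. Of 19 p53 targets 12 fell and 2 rose (14 and 2 over the list alone; Ccng1 at -1.49; camera adjusted p = 0.00297, adjusted p = 0.462 with an estimated correlation), and of 9 immediate early genes 7 fell (also over the list alone; Jun at -2.26; camera adjusted p = 0.0180, adjusted p = 0.509 with an estimated correlation). Of 10 B and plasma cell genes 4 fell, with Ms4a1 at -3.64, and of 11 adipocyte genes 1 rose (4 and 0 over the list alone; Pparg at 1.84; camera adjusted p = 0.0494 and 0.0458, adjusted p = 0.650 each with an estimated correlation). The 8 other lists were cortical epithelium, mimetic epithelium, double-negative thymocytes, eosinophils, brown fat, muscle, parathyroid and thyroid, and erythroid cells. Their camera adjusted p ran from 0.0515 (brown fat) to 0.980 (mimetic epithelium, where camera's direction was down and fry's up). Cortical epithelium had a median of 0.19 with camera's direction down, Ctsl at -0.98 and Cxcl12 at -0.68. Members of these lists that passed included Ptcra (5.38), Lrmp (3.11) and Mylpf (2.52), which rose, and Hes1 (-1.36), Il13 (-2.25) and Calca (-2.70), which fell. Aire fell by 0.85 (adjusted p = 0.0143), and Foxn1 was at -0.84 (adjusted p = 0.0951).

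From day 4 to day 7 most tested genes of double-positive thymocytes rose, while most of macrophages, fibroblasts, MHC class II and medullary epithelium fell. Ccr9, the receptor for Ccl25, rose by 5.36 (SE 0.31), Rag1 by 4.76 (SE 0.31), Rag2 by 3.73 and Cd4 by 3.08. C1qa was at -1.66 (SE 0.20), Il7 at -1.39 (SE 0.21), Il2ra at -1.14 (SE 0.20) and Ccl21a at -1.78 (SE 0.21). Of 13724 genes 3203 passed, 1590 higher and 1613 lower (edgeR quasi-likelihood), and 5114 had an unadjusted p under 0.05. The higher genes were the more numerous without the 18-month day 4 (592 higher, 416 lower) or day 7 section (1060 and 750), without age in the model (1177 and 896) and in cortical and medullary spots alone (1385 and 1358). Slc6a19 had 0 UMIs on day 4 and 268 on day 7, at least 88.8-fold higher (adjusted p = 0.000377). The other largest increases were Hba-a2 (6.15), BC028471 (6.05), Tdrd5 (5.39), Spo11, a meiotic recombination enzyme (4.77), and Chrna9 (4.64). The largest decreases were Glycam1 (-5.20, from the 18-month pair alone, 364 to 8 UMIs, with 0 at 2 months), Spink1 (-3.22), Lyz1 (-2.71), Lypd8 (-2.63), Aoc1 (-2.60), Fcgr4 (-2.57), Zfp750, a regulator of keratinization (-2.55), and Cilp (-2.53).

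Between days 4 and 7, 15 lists passed by camera (2 higher, 13 lower), 4 by fry and 0 with an estimated correlation. Of 10 double-positive genes 9 rose (median 3.51, camera adjusted p = 9.35e-32), of 10 macrophage genes 8 fell (median -1.36, 7.88e-08) and of 13 fibroblast and matrix genes 9 fell (Pi16 at -1.34; median -1.16, 1.49e-06), with adjusted p = 0.373 with an estimated correlation for each. Adjusted over the list alone the 3 counts were 10, 10 and 10. Of 12 medullary epithelial genes 7 fell (Krt5 at -1.45), of 11 endothelial genes 6, of 9 dendritic cell genes 4, of 11 regulatory T cell genes 2 with 1 higher (Ikzf2 at 0.61), and of 15 repair factors 7 (Wnt4 at -0.91), while 2 of 4 erythroid genes rose (Hbb-bt at 4.44). Adjusted over the list alone the counts were 8, 9, 4, 2 with 1 higher, 8 and 3. For these 6 lists the adjusted p = 0.436 with an estimated correlation, and the camera adjusted p was 2.68e-06, 0.000644, 0.0194, 0.0276, 0.000644 and 6.64e-08. Of 8 MHC class II genes 7 fell and of 10 mature T cell genes 7 fell (8 each over the list alone; camera adjusted p = 5.98e-05 and 4.50e-05, adjusted p = 0.441 each with an estimated correlation). Interferon (4 of 11 fell, 5 over the list alone), senescence and inflammation (2 of 9, 2 over the list alone) and mesenchymal transition (7 of 11 fell and 1 rose, the same over the list alone) had camera adjusted p = 4.50e-05, 0.00487 and 0.00607, and adjusted p = 0.562 with an estimated correlation. Of 10 cortical epithelial genes 2 fell (1 over the list alone; camera adjusted p = 0.0276, adjusted p = 0.695 with an estimated correlation). The 13 other lists had camera adjusted p from 0.0530 (tissue regulatory T cells) to 0.740 (mimetic epithelium and p53 targets). Of 19 p53 targets 4 rose (Btg2 at 2.27, Fas at 1.62, Trp53inp1 at 1.58) and 5 fell (Cdkn1a at -1.45), and Egr1 rose by 1.57. Xist was at 0.78 (adjusted p = 0.0353). The count was 1725 by DESeq2, 2073 without age in the model, and 1008 to 1810 without one of the 4 sections of days 4 and 7.

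**Figure D4:**
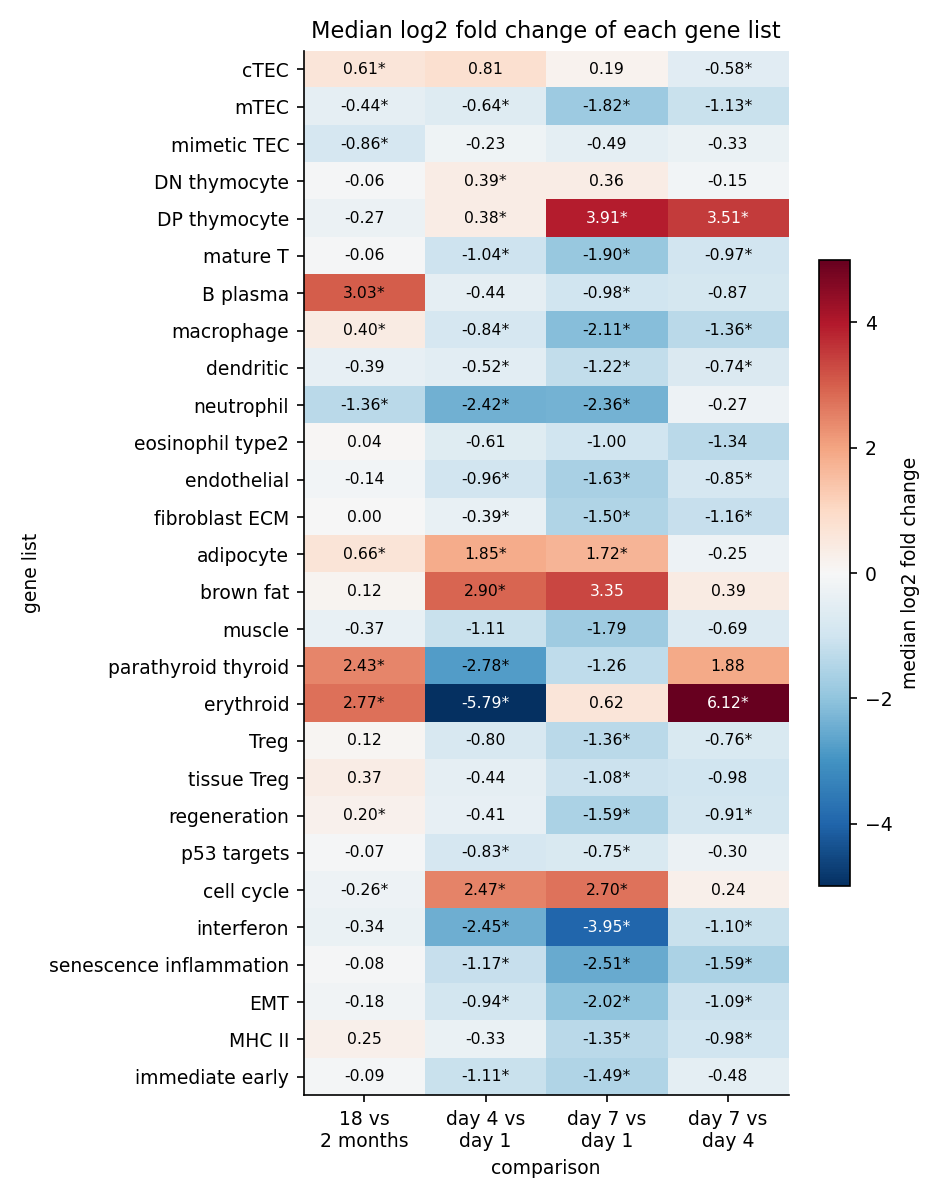
Median fitted log2 fold change of each of the 28 gene lists in 4 comparisons of whole sections (18 against 2 months, and the 3 pairs of days); a star marks camera adjusted p under 0.05 with the preset correlation, and none passed with an estimated correlation. The B and plasma cell list stands at 3.03 for age, and the double-positive list at 3.91 for day 7 against day 1.

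Areg and Il22, which encode amphiregulin and interleukin 22, lay under the count filter and were not tested. In the 2-month day 1 section Areg had 13 UMIs (2.10 CPM, 1.12 to 3.59) and Il22 had 15 (2.42 CPM, 1.36 to 3.997). In the 18-month day 1 section Areg had 2 UMIs (0.371 CPM, 0.0449 to 1.34) and Il22 had 1 (0.186 CPM, 0.00470 to 1.03). Neither gene had a UMI on day 4 at either age or on day 7 at 2 months, and each had 1 UMI in the 18-month day 7 section. Within 1 pair of sections these values carry counting error alone.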

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

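The values in this part come from a planned comparison, and the tests of explanations given further down for 3 patterns are in the part on other observations. The age difference differed between the medullary and the cortical region for 24 genes (edgeR quasi-likelihood interaction), and this tested difference between the 2 regions is what singled out every value in this part. The age difference was more positive in the medullary region for Hba-a1 (3.41), Ccl7 (2.51), Ccl2 (2.44), Pdpn (2.35), Rsad2 (2.03), Fcgr1 (2.00), Ecm1 (1.85) and Ccl8 (1.54), on the log2 scale. It was also more positive for the B and plasma cell genes Ighm (1.59), Igkc (1.58) and Jchain (1.11). Of these, Ccl2 and Fcgr1 were among the 10 leading genes of the cortical cluster of the 2-month day 1 section. The medullary cluster of the 18-month day 7 section had erythroid genes at 1.89 and B and plasma cell genes at 1.20 against the rest of that section. At resolution 1, where 5 sections held both regions, Ccl2 and Jchain turned to -0.67 and -0.18. There 28 genes passed, 7 of them among the 24, and without the 2-month or the 18-month day 1 section 8 of the 24 did. The age difference was more negative in the medullary region for Mgat5b (-3.33), Cyp2a5 (-2.97), Scx (-2.95), Sbsn (-2.13), Tnfrsf4 (-2.06), Cst6 (-1.89), Fcgbp (-1.57), Eppk1 (-1.51) and Lrmp (-1.16).

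For this count the 10 splits of the 6 sections are too few for a share under 0.05. The real value was 24 and the highest other 330, with 3 splits at 24 or more, the real one included. The others gave 330 each and are the same contrast of the 2 day 1 sections once day is in the model, so 1 contrast is counted more than once. A split that calls several times the real count points to a structure of the samples.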

How the results depend on the processing

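The tests without immunoglobulin genes and without both day 1 sections were chosen only after the result was seen, and the other alternatives were planned. The cause was not tested for any difference below. In tests of age, leaving out either section of a day takes that whole day out of the age difference, so these fits are not separate checks of single sections. In tests of days, a lone section is assumed to vary like the others. For age in whole sections (255 genes), 737 passed without a count filter, 124 in cortical and medullary spots, 15 with day as a linear number and 0 without day (edgeR; 190 at an unadjusted p under 0.05), while DESeq2 called 170 and limma-voom 253 with day. With a section left out 175 to 357 passed. For day 4 against day 1 (3813), DESeq2 called 2263, and leaving out a section gave 1173 (without 2-month day 4) to 4372, with 2169 without 18-month day 4. For day 7 against day 4 (3203), DESeq2 called 1725 and the model without age 2073, and leaving out a section gave 1008 (18-month day 4) to 4742, with 1492 without 2-month day 4, 1543 without 2-month day 7 and 1810 without 18-month day 7. For day 7 against day 1 (8012), leaving out a section gave 5966 to 7844.

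In the cortical region (20), 199 passed without a filter, 37 by limma-voom, 29 by DESeq2, 1 with linear day, 0 without day (edgeR; 41 at an unadjusted p under 0.05), 82 and 70 at resolutions 0.3 and 1 (5 sections each, as the 2-month day 1 section had 0 cortical spots), and 59 without both day 1 sections. Leaving out a section there gave 63 to 124: 70 (2-month day 1), 68 (18-month day 1), 80 (2-month day 4), 124 (18-month day 4), 64 (2-month day 7) and 63 (18-month day 7). In the medullary region (161), 368 passed without a filter, 65 by DESeq2, 4 without day and 279 with regions by score, and 115 to 426 with a section left out (242 without 2-month and 426 without 18-month day 7). For medullary against cortical (22), 34 passed without a filter, 67 and 64 at resolutions 0.3 and 1 (3 and 5 sections), 36 with regions by score and 4 without the section block, and 15 to 49 with a section left out (49 without 2-month day 1). For age by region (24), 71 passed without a filter, 11 by DESeq2 and 53 with regions by score, and 23 to 98 with a section left out (92, 98, 52 and 45 without 2-month day 4, 18-month day 4, 2-month day 7 and 18-month day 7). Resolution 0.3 was not run for age in the medullary region, where 4 sections had medullary spots, or for age by region, where 3 had both regions.

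Of the lists by age (11), 0 passed with an estimated correlation and 0 by fry, and 10 to 16 by camera with a section left out. Of the lists by day (54), 0 and 21 did, and 53 to 60 with a section left out. The medullary share by age (-1.83 points) became 2.97 without day 1, 0.792 at resolution 1 and 3.02 of cortical and medullary spots. Signs also turned for Dll4 between regions (-1.45 with regions by score), and for Ccl2 (-0.67) and Jchain (-0.18) in age by region at resolution 1. The brown fat list turned for age (adjusted p = 3.47e-07 and 5.66e-07 without the 2-month and the 18-month day 1 section, 0.466 with both, and 3.47e-07 to 0.178 over the left-out sections), and cortical epithelium for day 7 against day 1 (0.0458 without 18-month day 1, 0.942 with it, and 0.0458 to 0.948 over the left-out sections). Of all list tests under alternatives, 146 were weaker and 52 stronger.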

Other observations

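The test of depth, the test of macrophage genes within the medullary region and the splits were chosen beforehand, and the other tests in this part were chosen only after the result was seen. Each explanation had a bound on the values it allows and a stricter bound that counts against it. It was taken as argued against where the value passed the stricter bound and the whole 95% bootstrap interval over genes lay outside the allowed values. For depth, the change from full depth had to keep its interval within the bound. This use of intervals was settled, and once revised, after the values had been seen. The intervals treat the genes of a list as independent and leave out the spread between sections. They therefore do not show how a median would vary in other sections.

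In the deposited tables of Moran's I, Ccl21a led the 2-month day 1 section (0.557) and stood at 0.518 in the 2-month day 7 section, behind Scd1 (0.519). Igkc (0.482) and Ighm (0.475) led the 18-month day 1 section. The fat genes Cfd (0.724) and Ucp1 (0.722) led the 2-month day 4 section, and Cfd the 18-month day 4 section (0.608). The adjusted p of Foxp3 was 0.979, 0.988, 0.0867, 0.985 and 0.995 in the 2- and 18-month day 1, the 2- and 18-month day 4 and the 2-month day 7 sections, over spots. Saturation was 84.0%, 82.4%, 71.3%, 78.6% and 85.7% in the same order, and the share of reads in tissue spots 67.8%, 64.9%, 34.7%, 53.2% and 28.4%.

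The first pattern is the higher level of B cell genes in 18-month sections. Spots outside the 2 regions and a few immunoglobulin genes taking much of the counts could each contribute. In cortical and medullary spots alone the list median was 2.70 (interval 0.987 to 3.28), and without immunoglobulin genes that of the other members was 2.24 (0.898 to 3.06). The explanations allow medians under 0.5 and the bound against them was 1, so these values argue against each as the whole cause, although both intervals reach just below 1. Without immunoglobulin genes Cd79a was at 3.10 and Ms4a1 at 3.01. An effect of age, and a lymph node attached to the section, also stay open and were not tested.

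The second pattern is the lower level of mimetic epithelial genes in 18-month sections, where the 3 of 10 that passed in whole sections (Trpm5, Avil and Gnb3) are genes of tuft cells. A difference in depth could produce it. With all sections thinned to the smallest total the list median was -0.83 (interval -2.42 to -0.401) against -0.86 at full depth. Depth allows a median above -0.4, which the interval clears by very little. The bound against it was a change of at most 0.3, and the change was 0.0239 (-0.0796 to 0.256). This meets the rule, but thinning keeps the expected share of each gene, so a small change was likely whatever the cause. The values show only that unequal totals in the calculation do not make the difference, and depth is not otherwise decided. A smaller share of medullary spots allows a median above -0.5 within the medullary region. The rule for that region uses this list and left out a cluster with these genes in the 18-month day 1 section. With such clusters kept the median was -1.40 (-3.69 to -0.53), which argues against that share as the whole cause over the 3 days. Regions by score do not use the list, and there the median was -1.09 (-3.13 to -0.56). They take 25% of the spots of every section whatever its medullary share, so this value cannot decide about that share. In the medullary region drawn from clusters the median without both day 1 sections was -0.96 (-3.37 to -0.23), so that this test leaves days 4 and 7 alone open. On these days the medullary share was higher at 18 months (24.7% against 21.0%, and 16.2% against 14.0%), which goes against a smaller share, while at resolution 1 it was lower on day 4 (13.5% against 20.1%). An effect of age stays open and was not tested.

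The third pattern is the lower level of macrophage, vessel, fibroblast and interferon genes on day 7 than on day 1. Dilution by thymocyte RNA could lower all of them, and would lower cortical epithelial genes alike if their own share stayed level. Their median lay above that of macrophage genes by 2.30 (interval 1.18 to 3.40). The 2 medians were -0.26 and -3.06 within the cortical region, and 0.51 and -1.05 within the medullary region. But 5 cortical epithelial genes were higher and 5 lower in whole sections, and the cortical share of spots changed between the days. These values argue against dilution as the whole cause only if cortical epithelial genes are a stable reference, which was not tested. A larger share of cortical spots allows a median above -0.5 within either region. Within the cortical region the median of the 4 lists was -3.08 (-3.79 to -2.69), and -3.05 (-3.49 to -2.62) without the 2-month day 1 section. The macrophage, vessel and fibroblast lists entered the clustering and the checks that left clusters out, so the regions partly set their levels there. Interferon genes entered neither. Within the medullary region macrophage genes were at -1.05 (-1.69 to -0.63) and interferon genes at -2.27 (-2.70 to -1.83). Both met the rule, and for interferon genes this argues against that share as the whole cause. Vessel genes (-0.05) and fibroblast genes (-0.45) lay among the values that share allows there. Within the cortical region they were at -3.09 (-4.41 to -2.15) and -2.46 (-2.83 to -2.10), and without the 2-month day 1 section at -2.72 (-4.21 to -2.23) and -2.75 (-3.23 to -2.05). These values met the rule too. For macrophage, vessel and fibroblast genes the share stays open, because the regions partly set their levels. An effect of the days after injury stays open and was not tested.

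For comparisons of 3 sections against 3, the 10 splits are too few for a share under 0.05. For age in whole sections the real value was 255 and the highest other 199, with 1 split as large, the real one included. In the cortical region these were 20 and 1131 (3 splits), in the medullary region 161 and 32 (1 split), and for gene lists 11 and 20 (5 splits). With day in the model, splits that keep both sections of a day on 1 side repeat the same contrast in pairs. The 10 splits therefore hold fewer distinct contrasts, and the counts for the cortical region and for lists hold the day 1 contrast more than once. The splits that call several times the real count in the cortical region point to a structure of the samples, in which the 2 day 1 sections differ most. For medullary against cortical regions, 3 of 32 exchanges of regions within sections gave as many genes as the real 22, the highest other being 52, so that chance cannot be excluded.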
